A study of Mus musculus with 9 samples.

How the data were processed

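RNA was measured in 9 libraries of cDC1 sorted by flow cytometry from mouse mesenteric lymph nodes. Per the labels' protocols, cells were stained with antibodies that included CD45, CD3, CD19, B220, TER-119, NK-1.1, CD11b, CD64, F4/80 and SIRPa beside the markers of the sort gate. Dead cells and aggregates were excluded. Per the same protocols, total RNA was extracted with an on-column DNase step and amplified into double-stranded cDNA by single primer isothermal amplification, and libraries were sequenced as 50 bp single reads. Such amplification precedes sequencing without molecular identifiers, so counts are not counts of independent molecules.

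Per the submitters' processing notes, FastQC, STAR 2.4.2a and the GRCm38 genome build were used. Each deposited table held whole-number counts of reads per gene in the layout of STAR's gene counting, with an unstranded column and 2 stranded columns, and no normalisation. The annotation release and the alignment options were not given in the sources used here. The first-strand column held 48.8 to 50.4% of the stranded counts, so the unstranded column was used, and reads of overlapping or antisense genes could not be told apart. The 4 summary lines of each table name no gene and were left out of library sizes and tests. They held 5.35 to 9.47% (unmapped), 7.85 to 13.9% (multimapping), 22.6 to 42.3% (outside genes) and 4.76 to 9.89% (ambiguous) of the reads, and 36.4 to 53.1% were assigned to a gene. Because reads that map to several places were not counted to genes, the share of each gene's 50-base words found in another annotated transcript was computed as a measure of lost reads.

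The tables listed 48526 gene identifiers, of which 48144 (99.2%) matched GENCODE M21, an annotation on GRCm38. Symbols, coordinates (1-based), biotypes and exon lengths were taken from it. No count was found for 23956 genes in any library. Of 682 list symbols 655 matched, over 34 lists, and for 2 symbols with 2 identifiers the one with more counts was used. CPM were computed from TMM-scaled library sizes (edgeR 4.0.16, R 4.3.3), and levels compared between genes were log2(CPM per kilobase of exon + 0.1).

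The labels gave 1 group, so genes were compared within libraries and libraries with each other. The median level of the cDC1 identity list was set against 13 lists of other cell types, and 16 gene pairs were compared, by exact two-sided sign-flip permutation tests over the 9 libraries (512 flips). Excess variation between libraries was tested with edgeR's quasi-likelihood fit (intercept only, robust, filterByExpr with a minimum count of 10). Each gene's quasi-dispersion was set against the abundance trend in an upper-tail F test. Enrichment of lists among genes past the threshold used Fisher's exact test, one-sided, with the tested genes as background. List scores were means of log2 CPM (prior count 2) over tested members. Their SD over libraries was set against 10000 random lists matched on size and on 20 abundance bins, one-sided, for 23 lists of at least 5 tested genes. Pearson and Spearman correlations of 12 fixed pairs of scores or technical measures used all 362880 pairings, two-sided. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Computations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

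The lists, pairs, tests, most alternatives and the rule for named genes were set before the data were examined. The rule took all genes of the pairs, up to 10 of the most abundant members of the cDC1 identity and maturation lists, and 2 to 4 of every other list. It also took the 10 most abundant genes, genes past the excess variation threshold (and list members past it), Xist and the Y-linked list. Genes named outside it, among them those past the threshold over a list alone, were chosen after their values were seen. Other lists covered antigen presentation, pattern recognition, cytokines, retinoid and TGF-beta regulation, interferon-stimulated, immediate early, heat shock, cell cycle, histone, sterol, glycolysis, mitochondrial, ribosomal, noncoding and housekeeping genes.

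The numbers in the deposited table names fell into 3 runs of 3 consecutive numbers (libraries 1 to 3, 4 to 6 and 7 to 9). The labels give these numbers no meaning, and they were used only as a possible technical batch. Spearman correlations averaged 0.901 within runs and 0.882 between them, a gap of 0.019, and 1 of the 280 arrangements of the libraries into 3 sets of 3 (the runs themselves) gave a gap as large, the highest other being 0.016. Run by run the values were 0.887, 0.848 and 0.967, so libraries 7 to 9 carried the gap, and libraries 4 to 6 lay below the mean between runs. Within-run values stand beside each correlation for that reason. The biological coefficient of variation was 0.431 over all libraries, 0.395 with runs as a block, and 0.417, 0.495 and 0.216 within the runs.

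The excess variation, list covariation and sign-flip tests were tried on simulated data, while the correlations, enrichment, DESeq2 outliers and Dixon's ratio were not. Counts for the 8013 tested genes were drawn from the real means, library sizes and trend, and 200 genes had extra spread. The excess variation test, with its filter applied anew, recovered 46% of genes with an SD of 2 log2 units. It recovered 50.7% of those with an SD of 3. Genes removed by the filter counted as missed in both rates. The test made a mean of 2 false calls among 98.7 over 3 draws. For the list covariation test, the libraries of each of the same 8013 genes were first shuffled on their own, which removed correlation between genes. The test then found 10 of 10 lists of 15 genes given a shared shift with an SD of 0.3. It made 0 false calls among 190 other lists, of which 6.32% had an unadjusted p under 0.05. These rates hold for genes that vary independently and were not measured for genes correlated as in the real libraries. The sign-flip test gave a p under 0.05 in 3.70% of 2000 simulated sets with no difference.

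Alternatives were DESeq2 1.42.0 size factors or total counts in place of TMM, no filter or a mean of 50 counts, a non-robust fit, DESeq2 dispersion outliers, runs as a block or centring within runs, and the sum of the stranded columns. Further alternatives were no length division, a pseudocount of 1, a prior count of 0.5, means for medians and medians for means, and leaving out each library. Added after seeing the data were fits without libraries 4 and 5, covariation centred within runs, 2 further enrichment backgrounds or calls, and correlations over all members at 1 CPM.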

Results

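The series profiled conventional dendritic cells of lineage 1 (cDC1), the subset known for presenting antigen to CD8 T cells, from mesenteric lymph nodes (MLN), which drain the gut. CD11c+ MHC class II-high XCR1+ CD103+ cells were sorted by flow cytometry from untreated female C57BL6 mice of 7 to 10 weeks. The labels put all 9 libraries in 1 group, so the design held no contrast between conditions. The data were examined for which transcripts the sorted cells contained, how genes of dendritic cell subsets and of other cell types compared within the same libraries, and how uniform the 9 libraries were. The labels count 9 nodes but do not tie each library to its own mouse. P-values of the tests over libraries therefore measured the spread between these samples, which may be partly technical. Tests against random lists and Fisher's exact tests took genes as their units instead. Libraries are named by their replicate numbers, 1 to 9, as the labels gave them.

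The libraries held 23536255 to 32981078 reads each, of which 9345959 to 14907874 were assigned to genes (mean 12295047 ± 1898024, SD, n = 9). At 1 CPM, the usual count unit relative to library size, a gene had 10.02 to 14.4 counts in a library after TMM scaling. Between 14837 and 18048 genes had a count in each library, and 11768 genes averaged 1 CPM or more. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 38.6 over 36 pairs). That test covers counting error only, so repeat amplifications of 1 RNA are not excluded, and the 9 libraries were kept separate as labelled. Rank correlations between libraries over the tested genes ran from 0.813 to 0.969, with a median of 0.887 (across genes, which are not independent replicates).

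Mitochondrial ribosomal RNA took 32.9% ± 6.55 of the gene counts (SD, n = 9; 23.3 to 42.5%), with mt-Rnr2 at 237527 ± 71246 CPM and mt-Rnr1 at 105996 ± 56046 CPM (SD, n = 9, as for all CPM values that follow). The nuclear long noncoding RNA Malat1 followed with 40967 ± 18422 CPM. Next came B2m, the light chain of MHC class I, at 10568 ± 4254 CPM and mt-Co1, a subunit of cytochrome c oxidase, at 6969 ± 4993 CPM. Cd74, the MHC class II invariant chain, stood at 6197 ± 3305 CPM, the cytoskeletal gene Actb at 5984 ± 1938 CPM and Tmem123, a surface protein high in migrating dendritic cells, at 5053 ± 1708 CPM. The class I heavy chain H2-K1 (4944 ± 1137 CPM) and the actin-binding Tmsb4x (4081 ± 586 CPM) completed the 10 most abundant genes. Of 15 mitochondrially encoded genes, 9 reached 1 CPM, and 6 had at most 1 count over all libraries: mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l. Of the 14 matched housekeeping genes all reached 1 CPM, as did all 36 ribosomal protein genes, led by Rpl4 (416 ± 128 CPM) and Rps3 (203 ± 46.8 CPM). The median of the ribosomal protein genes was 20.6 CPM. Reads that map to several places were not counted. Levels and rankings of genes that share sequence with others are therefore uncertain, here and in the lists below. Of 15 matched genes of the noncoding list, which mixes long and small RNAs, 5 reached 1 CPM, among them Malat1, Xist and Neat1 (1227 ± 689 CPM).

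Transcripts of cDC1 identity were present in every library. Of 35 matched genes of this list, 33 reached 1 CPM, 25 reached 10 CPM and 8 reached 100 CPM. Flt3, the receptor for the growth factor that drives dendritic cell development, was highest at 444 ± 57.7 CPM, followed by Irf8, the transcription factor that specifies cDC1 (408 ± 140.0 CPM). The endocytic receptor gene Ly75 (382 ± 94.97 CPM) and the transcription factor genes Bcl6 (307 ± 69.3 CPM), Id2 (299 ± 58.8 CPM) and Zbtb46 (152 ± 45.5 CPM) lay in the same range. Itgb8, an integrin chain that activates TGF-beta, reached 248 ± 44.5 CPM and the inhibitory receptor gene Btla 131 ± 54.2 CPM. Wdfy4, needed for cross-presentation, averaged 75.1 ± 44.0 CPM and the lysosomal enzyme gene Ppt1 75.0 ± 56.0 CPM. Of the genes for the proteins used in the sort, the chemokine receptor gene Xcr1 (ENSMUSG00000060509, chromosome 9, 123852315 to 123862029) averaged 46.0 ± 23.2 CPM. It ranged from 13.7 CPM in library 5 to 83.7 CPM in library 1. Itgae, which encodes CD103 (chromosome 11, 73090583 to 73147446), averaged 14.0 ± 8.32 CPM.

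The cDC1 list stood above the markers of all 13 other cell types tested. The median cDC1 gene lay at 3.08 ± 0.69 (SD, n = 9) on the scale log2(CPM per kilobase of exon + 0.1). It exceeded the cDC2 list by 4.84 ± 1.18 log2 units, plasmacytoid dendritic cells (pDC) by 3.56 ± 1.15, monocytes and macrophages by 4.35 ± 0.96, T cells by 4.16 ± 2.12 and NK cells and innate lymphoid cells by 5.29 ± 1.56. These 5 differences were positive in 9 of 9 libraries. The B cell list was lower in 8 of 9 libraries (difference 3.00 ± 1.67) and the plasma cell list in 7 of 9 (1.65 ± 1.35). Library 5 was the exception for B cells, and libraries 4 and 5 for plasma cells. Neutrophil, mast cell and erythroid lists had medians at the floor of the scale in every library, so their difference of 6.40 ± 0.69 was set by the pseudocount. Stromal (6.31 ± 0.80), endothelial (6.10 ± 0.71) and epithelial lists (6.08 ± 0.90) lay close to that floor. With a pseudocount of 1 the other differences shrank too, to 2.94 for cDC2, 2.50 for pDC, 2.80 for monocytes and macrophages, 2.59 for T cells, 3.00 for NK and innate lymphoid cells, 2.14 for B cells and 1.33 for plasma cells. Exact two-sided sign-flip permutation tests gave adjusted p = 0.0046 for 11 lists, 0.0085 for B cells and 0.016 for plasma cells (Benjamini-Hochberg over 13 lists, n = 9). The smallest unadjusted p that 9 libraries allow is 0.0039. For the neutrophil, mast cell and erythroid lists that p was fixed by the floor, because the cDC1 median lay above it in every library. The stromal, endothelial and epithelial lists came near to this.

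**Figure D1:**
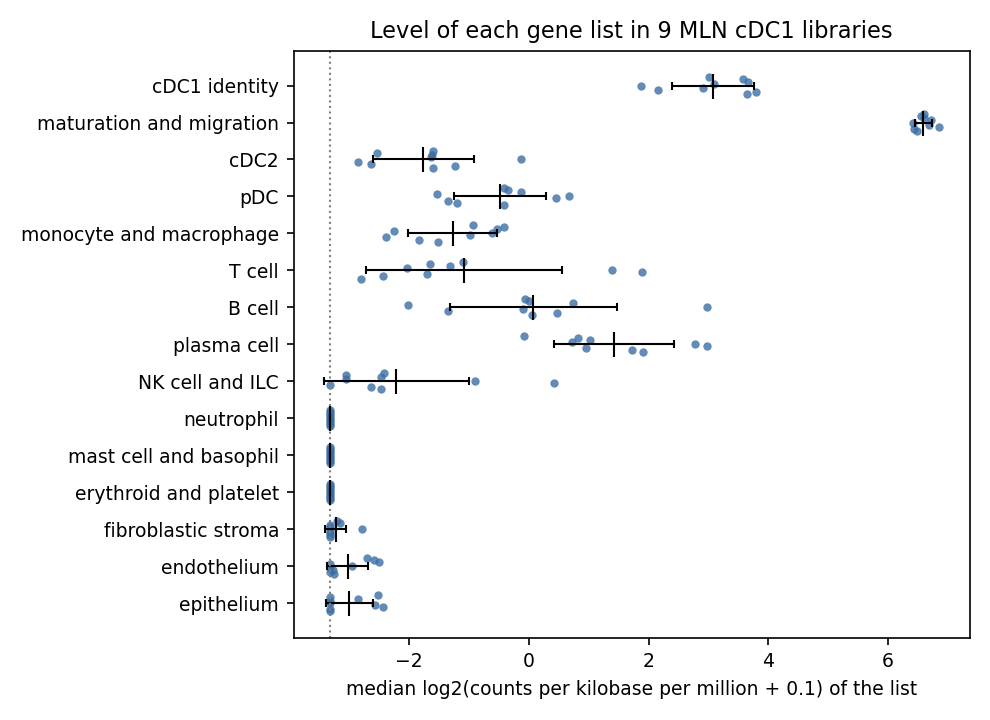
Median level of each gene list, as log2(CPM per kilobase of exon + 0.1), with 1 point per library, a tick at the mean and a bar of 1 SD (n = 9); the dotted line is the level of a gene with no counts. The cDC1 identity list averaged 3.08 and the maturation and migration list 6.59, while the T cell list reached 1.88 in library 4 and the B cell list 2.97 in library 5.

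Single genes of the other cell types were nonetheless measurable. In the cDC2 list, 12 of 21 genes reached 1 CPM, led by the receptor gene Notch2 (157 ± 39.7 CPM) and the transcription factor gene Irf4 (111 ± 22.6 CPM). The pDC list had 7 of 13, led by Runx2 (124 ± 28.4 CPM) and Spib (109 ± 44.5 CPM), both transcription factor genes. The monocyte and macrophage list had 11 of 20, led by the adhesion molecule gene Vcam1 (102 ± 26.2 CPM) and the lysozyme gene Lyz2 (29.6 ± 9.59 CPM). Of 16 T cell genes 12 reached 1 CPM. Tcf7, a transcription factor gene, was at 421 ± 135 CPM in all libraries, while the T cell receptor complex gene Cd3e averaged 13.5 ± 24.3 CPM and reached 74.1 CPM in library 4. Of 15 B cell genes 13 reached 1 CPM, led by Ighm, the IgM heavy chain (161 ± 87.1 CPM), and Ighd (32.0 ± 22.9 CPM). Both were highest in library 5, at 368 and 88.2 CPM. Of 14 plasma cell genes 12 reached 1 CPM, led by the antibody chains Igkc (196 ± 200.4 CPM) and Igha (188 ± 241 CPM). Of 15 NK and innate lymphoid genes 6 reached 1 CPM, led by the cytokine receptor gene Il7r (176 ± 47.1 CPM) and Txk (12.2 ± 28.8 CPM). Txk, like Eomes, rested on library 4 (88.3 and 78.1 CPM there). The mast cell list had 1 of 10 (Kit, 29.5 ± 14.9 CPM), the erythroid and platelet list 1 of 12 (Alas2, 1.10 ± 1.11 CPM) and the neutrophil list 0 of 12 (Cxcr2 was highest, 0.954 ± 1.83 CPM). The stromal list had 2 of 13 (Cxcl13 and Bgn), the endothelial list 3 of 12 (led by Glycam1 and Pecam1) and the epithelial list 2 of 11 (Fabp2 and Vil1).

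Genes of dendritic cell maturation and migration were at higher levels than those of cDC1 identity. All 39 genes of this list reached 1 CPM, 38 reached 10 CPM and 31 reached 100 CPM, and the list median was 6.59 ± 0.14. The chemokine gene Ccl22 reached 3310.1 ± 1336 CPM and Ccr7, the receptor that guides dendritic cells to lymph nodes (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), 2808 ± 1154 CPM. Fscn1, an actin-bundling protein of mature dendritic cells, stood at 2480.2 ± 912 CPM. Further members were Serpinb6b (1871 ± 441 CPM), the calcium channel subunit gene Cacnb3 (1546 ± 226 CPM), the chemokine gene Ccl5 (1492 ± 429 CPM) and the granzyme inhibitor gene Serpinb9 (1281 ± 379 CPM). Cd274, which encodes PD-L1, stood at 1164 ± 415 CPM and the signalling adaptor gene Traf1 at 975 ± 166 CPM. Genes linked to lymph node-resident cDC1 were present too, since 11 of 12 reached 1 CPM. The necrotic-cell receptor gene Clec9a (67.7 ± 33.2 CPM), the interferon-induced chemokine gene Cxcl9 (63.1 ± 41.8 CPM), Xcr1 and Tlr11 (40.3 ± 10.6 CPM) led that list. The identity and resident lists share Clec9a, Xcr1, Tlr11 and Gpr33, and XCR1 was used in the sort. Ccr9 and Cd8b1 are also in the pDC and T cell lists. The count of resident genes at 1 CPM therefore does not show a separate resident population.

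Antigen presentation genes were abundant. All 22 class I genes reached 10 CPM (list median 6.33 ± 0.13), with H2-D1 at 2414 ± 583 CPM and the proteasome activator gene Psme1 at 1135 ± 257 CPM after B2m and H2-K1. All 16 class II genes reached 1 CPM (list median 3.85 ± 0.26). After Cd74, the class II chains H2-Aa and H2-Ab1 were at 862 ± 272 and 719 ± 206 CPM and the lysosomal thiol reductase gene Ifi30 at 628 ± 192 CPM. In the cross-presentation list, 16 of 19 genes reached 1 CPM, led by the peptide transporter gene Tap1 (458 ± 46.8 CPM) and Stx4a (166 ± 48.5 CPM). Pattern recognition genes were lower, with 17 of 25 at 1 CPM or more and none at 100 CPM. Tlr9, a sensor of unmethylated DNA (99.5 ± 36.4 CPM), and Tlr13, a sensor of bacterial ribosomal RNA (80.8 ± 31.3 CPM), led them. Among cytokine and chemokine genes 22 of 32 reached 1 CPM, with Cxcl16 at 729 ± 138 CPM after Ccl22 and Ccl5.

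Of 27 regulatory genes of retinoid and TGF-beta handling, 24 reached 1 CPM. Aldh1a2, which encodes the retinal dehydrogenase that makes retinoic acid (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243), was the highest at 1822 ± 904 CPM. It ranged from 614 CPM in library 6 to 2942 CPM in library 8. Cd274, the cytokine signalling inhibitor gene Socs2 (270.2 ± 49.5 CPM) and Itgb8 followed.

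**Figure D2:**
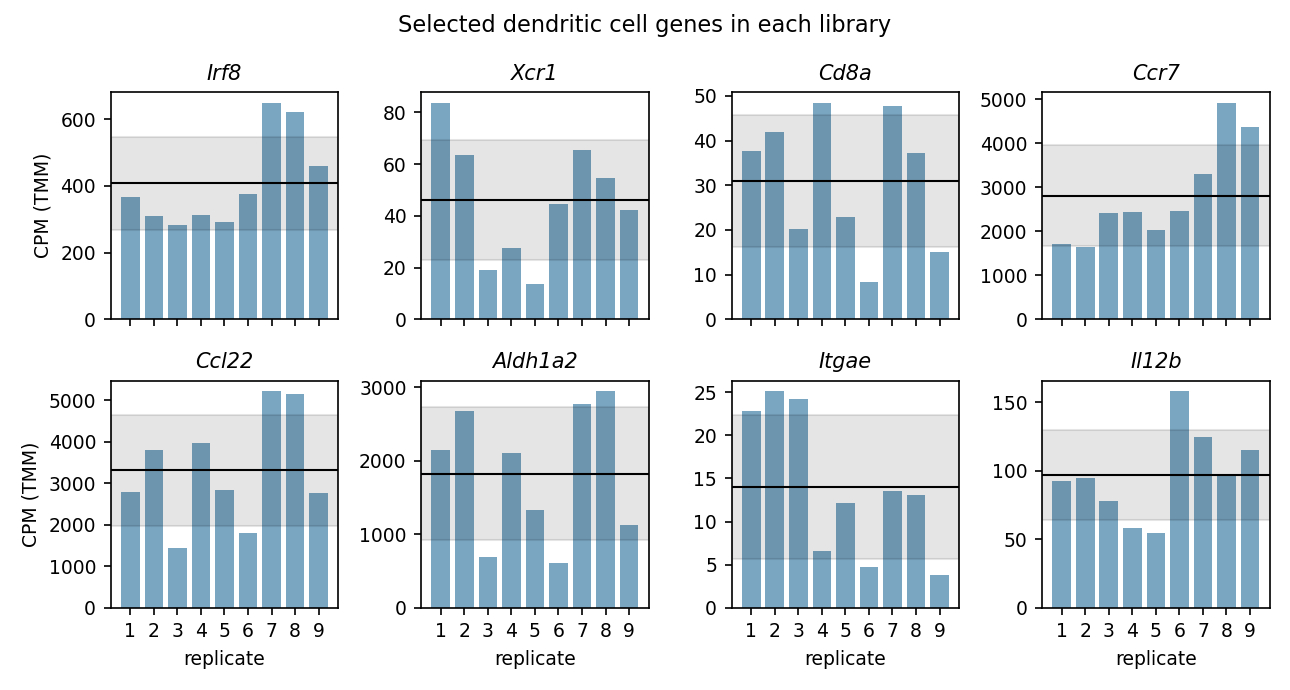
Normalised level of 8 dendritic cell genes in each library, in CPM after TMM scaling; bars are libraries 1 to 9, the line is the mean and the grey band 1 SD on either side. Aldh1a2 ran from 614 CPM in library 6 to 2942 CPM in library 8, and Ccr7 from 1650.1 CPM in library 2 to 4916 CPM in library 8.

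Among activity and metabolic programmes, immediate early genes were high. Of 25 genes 24 reached 1 CPM, led by Zfp36, which destabilises inflammatory mRNAs (2289 ± 988 CPM), the transcription factor gene Klf6 (2099 ± 588 CPM) and the phosphatase gene Dusp1 (1890.3 ± 1020.1 CPM). All 14 heat shock genes reached 1 CPM, led by the chaperone genes Hsp90ab1 (1581 ± 296 CPM) and Hspa8 (298 ± 48.7 CPM). Interferon-stimulated genes were lower, with 31 of 39 at 1 CPM and 3 at 100 CPM, namely the antiviral Mx1 (284 ± 72.9 CPM) and the signalling genes Stat2 (106 ± 13.9 CPM) and Stat1 (105 ± 17.5 CPM). Sterol and lipid genes numbered 24 of 26, led by Hmgcr, the rate-limiting enzyme of cholesterol synthesis (406 ± 127 CPM), and the sterol exporter gene Abcg1 (289 ± 57.5 CPM). Glycolysis and hypoxia genes numbered 18 of 22, led by Aldoa (145 ± 37.2 CPM) and Ndrg1 (121 ± 28.4 CPM). Of 40 cell cycle genes 36 reached 1 CPM but 7 reached 10 CPM, led by the proliferation marker Mki67 (156 ± 42.8 CPM) and the thymidine kinase gene Tk1 (83.1 ± 29.4 CPM). Replication histones numbered 7 of 28, led by the linker histone gene Hist1h1c (54.1 ± 24.1 CPM). Xist, expressed from the inactive X chromosome, stood at 3494 ± 1663 CPM (1506 to 5827), and the highest of 4 Y-linked genes, Uty, at 0.0689 ± 0.0851 CPM, beside the female label.

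Pairs of genes fixed in advance set cDC1 genes against genes of other subsets within the same library. Irf8 exceeded Irf4 by 1.32 ± 0.54 log2 units (SD, n = 9, per kilobase), Xcr1 exceeded Sirpa, a cDC2 surface receptor, by 4.04 ± 1.97, and Clec9a exceeded the lectin gene Clec10a by 7.21 ± 0.82. Flt3 exceeded Csf1r, the macrophage growth factor receptor, by 7.13 ± 1.25 and Tlr3 exceeded Tlr7 by 2.71 ± 1.82. Batf3, a cDC1 transcription factor gene, exceeded Klf4 by 1.15 ± 0.66. Ccr7 exceeded Gpr33 by 6.71 ± 0.59. Each of these 7 differences was positive in 9 of 9 libraries. Itgae exceeded Itgam, which encodes CD11b, by 2.73 ± 2.00 in 8 of 9 libraries (all but library 5), and it was lower than Cd8a, a marker of resident cDC1, in 9 of 9 (-1.52 ± 0.88). The class II chain H2-Ab1 was below the class I chain H2-K1 in 9 of 9 libraries (-2.61 ± 0.56). Library 5 was again the exception for the costimulatory pair, where Cd86 exceeded Cd80 in 8 of 9 libraries by 0.83 ± 0.66. Cd274 exceeded the second PD-1 ligand Pdcd1lg2 by 4.09 ± 0.60, Ccl22 exceeded its neighbour Ccl17 by 3.73 ± 0.81 and Il12b, a subunit of IL-12 and IL-23, exceeded Il10 by 6.30 ± 1.92, each in 9 of 9 libraries. Aldh1a1 had 0 counts in all libraries against 205002 for Aldh1a2, which was at least 149013-fold higher per kilobase against a floor of 3 counts over the group (9 of 9 libraries). That floor covers counting error only.

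Exact two-sided sign-flip permutation tests passed for 15 of the 16 pairs at an adjusted p of 0.0048, or 0.0083 for Itgae against Itgam and Cd86 against Cd80 (n = 9). The sort on XCR1 and CD103 favoured Xcr1 and Itgae, so tests of pairs and of the cDC1 list that hold these genes partly restate the gate. The staining panel also held antibodies to the products of Sirpa and Itgam, and to T cell and B cell markers. If cells bearing these were gated out, the contrasts with those genes and lists partly restate the sort too. Different genes can also differ in level in every library whatever the cell type, and no random pairs were tested. The number of pairs that passed therefore does not by itself show subset identity. Il15 and Il12b did not differ beyond the spread (-0.37 ± 0.63, Il15 higher in 3 of 9 libraries, exact permutation p = 0.117, adjusted p = 0.117). Sizes depended on the pseudocount where the lower gene was near the floor. With a pseudocount of 1, Clec9a exceeded Clec10a (10 counts in all) by 4.26, Tlr3 exceeded Tlr7 (60 counts) by 1.03, Itgae exceeded Itgam by 1.33, Xcr1 exceeded Sirpa by 2.64, Flt3 exceeded Csf1r by 5.60 and Il12b exceeded Il10 by 4.76. Without division by exon length, Tlr3 exceeded Tlr7 by 4.08 and Ccl22 exceeded Ccl17 by 5.91. In that setting the Batf3 difference was 0.22 and its call ended (adjusted p = 0.379 by the same exact test, n = 9). Without libraries 4 and 5, Il12b exceeded Il15 (-0.60, adjusted p = 0.047 by the exact permutation test, n = 7). Itgam shared 66.3% of its read-length words with other annotated genes, so its level is uncertain.

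Of 8013 genes tested for variation between libraries beyond that of genes of their abundance, 2 passed edgeR's quasi-likelihood test at an adjusted p under 0.05, and 338 had an unadjusted p under 0.05. The 338 are a share below 0.05. In simulation, 4.10% of genes given no extra spread had an unadjusted p under 0.05 in this edgeR test, so the 338 are near that rate. Aspscr1, a tether of glucose transporter vesicles (ENSMUSG00000025142, chromosome 11, 120672973 to 120709447), reached 495 CPM in library 6 and at most 36.5 CPM in the other 8 (edgeR adjusted p = 0.029). Igha, the IgA heavy chain constant region (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236), reached 784 CPM in library 4 and at most 240.4 CPM in the others (edgeR adjusted p = 0.029). Each call rested on its highest library: Igha had an edgeR adjusted p of 0.314 without library 4 and Aspscr1 of 0.966 without library 6, where Igha also missed (0.317). Without libraries 4 and 5 the count was 1, with runs of consecutive file numbers as a block 0, among genes averaging 50 counts 0, without a filter on low counts 97 of 24570, and DESeq2 marked 49 dispersion outliers. The common biological coefficient of variation was 0.431. The filter asks for the count cutoff in all 9 libraries. It therefore removes genes high in 1 library and near 0 in the others, and any gene low in 1 library. In simulation the filter and test together recovered 50.7% of genes given an SD of 3 log2 units, with genes lost to the filter counted as missed. The count of 2 therefore does not show that libraries were uniform. Cd3e, Eomes and Txk were untested because of the filter and passed without it (edgeR adjusted p = 0.0012, 2.93e-06 and 9.07e-05). The unfiltered fit also differed for genes tested in both, which made up 49 of its 97 calls, and its prior degrees of freedom were 27.8 instead of 9.57. The filter kept few lymphocyte genes, with 2 of 16 T cell, 5 of 15 B cell and 1 of 15 NK and innate lymphoid genes tested.

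Adjusted over the list alone, edgeR's p passed for 6 mitochondrial genes (mt-Co1, mt-Nd2, mt-Nd6, mt-Nd4, mt-Cytb and mt-Nd5), 2 plasma cell genes (Igha and Igkc), 2 B cell genes (Fcer2a and Ighm), 2 resident cDC1 genes (Ccr9 and Cxcl9) and 1 T cell gene (Trac). It also passed for Ccr9 in the pDC list and for Neat1 in the noncoding list. No adjustment was made over the 28 lists with a tested gene, so these passes are not set against chance over lists. In the 21 other lists with a tested gene it passed for 0 genes, with Ppt1 of the cDC1 identity list closest (edgeR adjusted p = 0.055 over that list). Over all genes tested, Aldh1a2 had an edgeR p of 0.0077 and an adjusted p of 0.966, and without a filter on low counts it passed (edgeR adjusted p = 0.011). Of 23 lists, 1 was enriched among the genes past the threshold, the plasma cell list with 1 of 7 tested members, Igha (Fisher's exact test, one-sided, adjusted p = 0.040). With 2 genes past the threshold, this restates the single Igha call and says nothing about plasma cell genes as a group. That enrichment was absent without library 4 and without library 6. Among the 49 DESeq2 outliers, the plasma cell list (Igha and Igkc) and the mitochondrial list (mt-Co1 and mt-Nd2) were enriched (adjusted p = 0.015, Fisher's exact test).

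Mean scores of several lists varied more across libraries than those of random lists. The mean cDC1 identity score had an SD of 0.378 log2 units (n = 9) against a median of 0.106 for random lists of equal size and abundance, and 22 of its 26 tested genes moved with the rest. It was lowest in library 5 (-0.56 from the mean) and highest in library 1 (0.40), while B cell and pDC scores were highest in library 5 (1.53 and 0.64 above their means). Library 3 had a cDC1 score of 5.32 (5.15 in library 5) with the lowest B cell score (3.28), and was the lowest for cDC1 identity after centring within runs (-0.52). No relation of the cDC1 score to these scores was tested. Cholesterol and lipid genes had an SD of 0.345 against 0.107, with 23 of 23 genes moving together, and mitochondrially encoded genes 0.643 against 0.150, with 9 of 9. Centred within runs, the mitochondrial SD fell to 0.377 (random median 0.098), so part of that spread lay between runs. The permutation p was 0.0001 for each of these 3, the smallest the 10000 random lists can give (adjusted p = 0.00077). For list scores, permutation means drawing random gene lists, and no libraries were permuted. Scores of B cell genes (SD 0.676), plasma cell genes (0.569) and pDC genes (0.423) also varied more than random lists, with permutation adjusted p of 0.0015, 0.0012 and 0.016. Of their tested genes, 5 of 5, 5 of 7 and 4 of 7 moved with the rest of the list. None of these 3 lists passed without libraries 4 and 5 (0.458, 0.123 and 0.245). B cell and pDC genes missed already without library 5 (0.244 and 0.057) and plasma cell genes without library 4 (0.051).

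Resident cDC1 genes (SD 0.432, adjusted p = 0.0014), MHC class II genes (0.328, adjusted p = 0.0039) and ribosomal protein genes (0.194, adjusted p = 0.012) passed the same permutation test against random gene lists. Ribosomal protein genes missed it without library 4 (0.071) or 6 (0.124). Immediate early genes had an SD of 0.240 (permutation adjusted p = 0.0046), which ended when scores were centred within runs of file numbers (adjusted p = 0.791). Heat shock genes (0.234, adjusted p = 0.021), cell cycle genes (0.333, adjusted p = 0.035), cytokine genes (0.259, adjusted p = 0.035) and pattern recognition genes (0.255, adjusted p = 0.046) passed by permutation, and each missed it without library 5 (adjusted p from 0.055 to 0.204). Heat shock genes also missed it without library 3 (0.061), cytokine genes without library 8 (0.059), and cell cycle genes without library 3, 4 or 8 (0.055 to 0.059). Pattern recognition genes missed it without library 3, 7 or 8 (0.067 to 0.394), within runs (0.099), with DESeq2 size factors (0.055) and among genes averaging 50 counts (0.084). In all, 14 of 23 lists passed, and 8 without library 5. Genes moving with the rest of their list were 8 of 9 (resident cDC1), 10 of 14 (MHC class II), 30 of 33 (ribosomal protein) and 16 of 22 (immediate early). They were 12 of 13 for heat shock, 9 of 13 for cell cycle, 9 of 12 for cytokine and 10 of 15 for pattern recognition genes. Maturation and migration (SD 0.137, permutation adjusted p = 0.133) and MHC class I genes (0.139, adjusted p = 0.214) did not pass, but did after centring within runs (adjusted p = 0.015 for both). Cross-presentation genes (0.230, permutation adjusted p = 0.064) passed without library 4 (0.035) and without libraries 4 and 5 (0.028). Regulatory (0.153, permutation adjusted p = 0.282), interferon-stimulated (0.148, 0.399), glycolysis (0.210, 0.282), cDC2 (0.225, 0.410), housekeeping (0.152, 0.417) and replication histone genes (0.273, 0.683) did not pass.

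**Figure D3:**
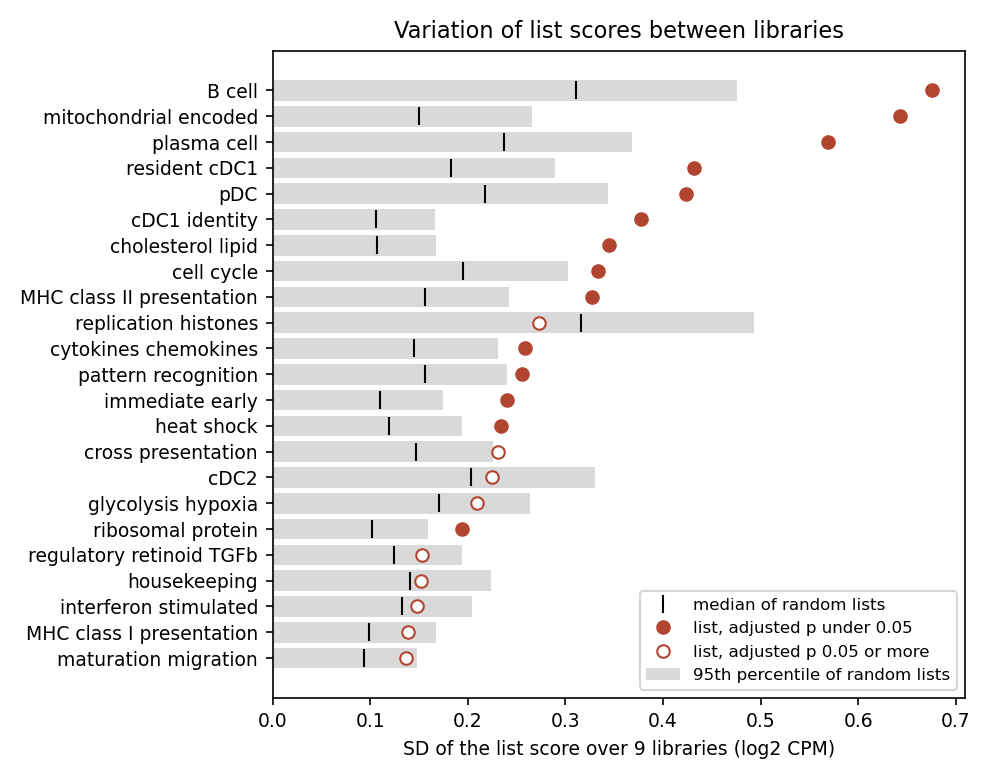
SD of the mean list score over the 9 libraries, in log2 CPM, as points (filled where the adjusted permutation p was under 0.05), beside the median (tick) and 95th percentile (end of the grey bar) of random lists matched on size and abundance. The mitochondrial list had an SD of 0.643 against a random median of 0.150, and the maturation and migration list 0.137 against 0.094.

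Of 12 relations between list scores or technical measures fixed in advance, 0 passed after Benjamini-Hochberg adjustment (exact two-sided permutation over all pairings, n = 9). Cholesterol and maturation scores had r = 0.71 (exact p = 0.035, adjusted 0.284) and rho = 0.72 (exact p = 0.037, adjusted 0.201), with r = 0.57 without the 2 libraries farthest from the median and r = 0.52 within runs of file numbers (exact p = 0.514). Immediate early and maturation scores had r = 0.68 (exact p = 0.049, adjusted 0.284) and rho = 0.70 (exact p = 0.043, adjusted 0.201), with r = 0.46 without the 2 farthest libraries and 0.55 within runs (exact p = 0.431). Without library 5 that relation had r = 0.93 and passed (exact permutation adjusted p = 0.013, n = 8). Maturation scores and the log2 count total had r = 0.62 (exact p = 0.076, adjusted 0.284) and rho = 0.68 (exact p = 0.050, adjusted 0.201), with 0.57 without the 2 farthest and 0.67 within runs (exact p = 0.208). The B cell and T cell scores, the latter from 2 tested genes, had r = 0.58 (exact p = 0.105, adjusted 0.284) and rho = 0.33 (exact p = 0.385, adjusted 0.771), and the relation rested on libraries 4 and 5, since r was -0.05 without them. Within runs it was 0.34 (exact p = 0.699).

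Cell cycle scores had r = -0.53 with maturation (exact p = 0.142, adjusted 0.284; rho -0.55, exact p = 0.133, adjusted 0.319) and r = -0.54 with replication histones (exact p = 0.139, adjusted 0.284; rho -0.62, exact p = 0.086, adjusted 0.257). These were -0.45 and -0.62 without the 2 farthest libraries, and -0.74 and -0.61 within runs (exact p = 0.106 and 0.148). The other 6 relations had r between -0.15 and 0.17 and rho between -0.15 and 0.17, with exact permutation p of at least 0.656 for r and 0.678 for rho (adjusted at least 0.795 and 0.991). They were cDC1 identity with maturation, resident cDC1 with maturation, maturation with MHC class II, interferon-stimulated genes with MHC class I, immediate early with heat shock, and the share of reads outside genes with mitochondrial genes. Without the 2 farthest libraries, r lay between -0.36 and 0.26 for these 6, and within runs between -0.51 and 0.62 (exact p at least 0.106).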

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

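Chosen after the result was seen were the tests of Aldh1a2 against runs of file numbers and against dilution, the simulation of independent peaks for T cell and B cell genes, and the test of mt-Atp8. Of 55 values tested for a library far from the other 8 (Dixon's ratio of gap to range), 5 stood apart. Without Aspscr1 and Igha, which were tested because they had passed the excess variation test, 3 of 53 did, where chance marks about 1 in 20. Unmapped reads were 9.47% in library 3 against 7.01% in the next. The stromal list median was -2.80 in library 5 (next -3.15) and the Y-linked list median -3.19 in library 6 (next -3.28), both close to the floor of -3.32. Aspscr1 stood at 495 CPM in library 6 (next 36.5 CPM) and Igha at 784 CPM in library 4 (next 240.4 CPM).

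T cell and B cell genes peaked in libraries 4 and 5, but not equally. The T cell list median was 1.88 in library 4 and 1.40 in library 5. The B cell list median was 2.97 in library 5 but -0.11 in library 4, below library 7 (0.74). The mean B cell score over tested genes was 5.64 in library 5 and 4.63 in library 4. Of 31 members of both lists with 10 counts or more, 30 had their highest level in library 4 or 5. The 95th percentile was 14 in 10000 simulations with independent peaks (none reached 30). This argues against single-gene noise spread independently over the libraries. Amplification noise concentrated in libraries 4 and 5 would also exceed that percentile, so the simulation cannot exclude it. Members of 7 other off-lineage lists peaked there in 20 of 55 cases (Fisher's exact test, one-sided, p = 7.44e-09). The 2 libraries were picked by the T and B peaks themselves, and genes are not independent replicates. This p therefore cannot decide whether the libraries were generally noisier. Genes outside all lists also peaked in library 4 (Dnaic2 had 100% of its CPM there), so noise of single genes in that library stays open. Library 4 had the fewest genes with a count of any library (14837, from 14777849 gene counts) and the highest multimapping share (13.9%). Its correlations with the other libraries ran from 0.813 to 0.878. RNA from lymphocytes or antibody-secreting cells, despite CD3, CD19, B220 and NK-1.1 antibodies in the staining panel, remains a candidate source, with Cd3e at 74.1, Trac at 41.8 and Eomes at 78.1 CPM in library 4, and Pax5 at 103 and Ighm at 368 CPM in library 5. Against a plain mixture, Cd3d (3.24 CPM) and Cd3g (4.58 CPM) stayed far below Cd3e in library 4, which keeps it open, and no biological explanation was tested, since the labels give 1 group.

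The retinal dehydrogenase gene Aldh1a2 was at 2144, 2672, 687, 2109.7, 1333, 614, 2768, 2942 and 1125 CPM in libraries 1 to 9. Runs of file numbers held little of this spread, since 0.839 of the sum of squares lay within runs (0.75 is the share with no run effect), and dilution of the whole library is argued against because the log2 ratio of Aldh1a2 to the maturation list spanned 2.41 while the list itself spanned 0.37. Amplification noise of this gene cannot be told apart from variation between the sorted cells: 76 genes followed Aldh1a2 with r over 0.9 within runs, at percentile 91.4 of 500 genes of its abundance, between the bounds set for either reading. The gene missed the excess variation threshold over the filtered genes (edgeR adjusted p = 0.966) and passed it without a filter (0.011), and no biological explanation was tested.

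Of 15 mitochondrial genes, 6 had at most 1 count over all libraries. For 5 of them (mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l), 98.0 to 99.9% of the 50-base words also occurred in nuclear pseudogenes on chromosome 1 (24612407 to 24615565), against at most 62.2% for mitochondrial genes with counts, so reads that match both places and were left out as multimapping are a candidate explanation. The prediction had asked for all 6, and mt-Atp8 shared 0% with annotated genes; the gap between mt-Co2 and mt-Atp6, where it lies, differed by 3 bases (230 against 233) from the gap between their nuclear copies, which is consistent with an unannotated copy. Overlap with neighbouring genes is argued against, since 6 of 6 had under 50% of their length under another gene (highest 21.1%). No biological explanation was tested.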

How the results depend on the processing

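Chosen after the result was seen were the fits without libraries 4 and 5, covariation centred within runs, enrichment among DESeq2 outliers or without a filter, and correlations over members at 1 CPM. No paired analysis was possible because the labels gave 1 group. All 13 list contrasts passed under every alternative run, those of lists at the floor by construction, and 14 to 16 gene pairs did. The count of genes with excess variation was 2, against 97 without a filter (24570 genes tested, prior degrees of freedom 27.8 instead of 9.57), 0 among genes averaging 50 counts, 0 with runs as a block, 1 without libraries 4 and 5, 49 with DESeq2 outliers, and 0 to 2 leaving out single libraries (1 without library 4, 0 without 6). Enriched lists numbered 1 (through the single Igha call), against 0 among genes averaging 50 counts, 2 with DESeq2 outliers, 7 without a filter and 0 to 1 leaving out single libraries. Lists whose mean score varied more than random lists numbered 14, with 8 to 14 leaving out single libraries (8 without library 5), 13 with DESeq2 size factors and 10 without libraries 4 and 5. Correlations past the threshold numbered 0, and 0 to 1 leaving out single libraries (immediate early with maturation without library 5). No correlation that turned sign passed the threshold in either setting. With medians of members, cDC1 identity with maturation gave r = -0.45 and immediate early with heat shock 0.64. Centred within runs, maturation with MHC class II gave -0.43 and immediate early with heat shock 0.62. Over members at 1 CPM, maturation with MHC class II gave -0.0024 and interferon-stimulated with MHC class I -0.012. Leaving out single libraries, r ran from -0.24 to 0.42 for cDC1 identity with maturation, -0.37 to 0.019 for resident cDC1 with maturation, -0.071 to 0.18 for maturation with MHC class II, -0.075 to 0.57 for interferon-stimulated with MHC class I, -0.29 to 0.10 for immediate early with heat shock and -0.33 to 0.10 for reads outside genes with mitochondrial genes. Of the 97 genes called without a filter, 49 had been tested with it too. For all changes in this paragraph the cause was not tested. Of the other single results, 839 kept their direction and side of the threshold, 35 missed it and 6 newly passed it. Depth limits genes under 10 counts in a library, which the filter leaves untested.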

Other observations

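The search for followers of Aldh1a2 and the genes named here were chosen after the values were seen, while the tests without a filter were planned. Without a filter on low counts, edgeR called 97 genes, of which 43 were highest in library 4 and 15 in library 5. Eomes, a transcription factor gene of cytotoxic lymphocytes, had 96.3% of its summed CPM in library 4, and Txk, a kinase gene of T and NK cells, 80.8%. Genes outside all lists were similarly concentrated there, among them Dnaic2 (100%), Pdzk1 (99.1%), Gbx1 (98.8%), Rflna (98.4%) and Stum (92.4%), so the pattern was not confined to lymphocyte genes. The antibody genes Ighg1 (57.9% in library 5) and Ighg2b (44.3% in library 2) peaked in different libraries, as did Aspscr1 (77.9% in library 6). The B cell coactivator gene Pou2af1 had 50.5% in library 5.

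Among genes of all kinds, the closest follower of Aldh1a2 across libraries, after centring within runs, was Ccl22 (r = 0.99), which encodes a chemokine that attracts regulatory T cells. Zc3h7b (r = 0.99) and Tnik (r = 0.98) followed. These correlations are the highest of 8013 genes and carry no test of their own. Other genes ran opposite to Aldh1a2 within runs, with Gm42031 at r = -0.99. Of the maturation list, which holds Ccl22, Eno2 (r = -0.96) and Tbc1d4 (r = -0.90) did so too.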
